A study of Mus musculus with 6 samples.

How the data were processed

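RNA from the atria of 6 old mice was measured by RNA sequencing, with 1 library per mouse. The labels give an average age of 20.9 ± 0.43 months, without saying what kind of error the second number is, and say that mice of both sexes were used. The design text names 3 knockout mice of protein kinase C epsilon (PKC-epsilon, encoded by Prkce) and 3 wild-type (WT) controls. Per the labels' protocols, flash-frozen atria were homogenised, RNA was isolated with RNeasy columns and libraries were made from 1 µg of total RNA with the TruSeq RNA Library Prep Kit v2, which does not mark strand.

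The deposited table holds raw counts of reads per Ensembl gene for 54838 genes and all 6 libraries, with no normalisation. Per the submitters' processing notes, the tools used were FastQC 0.11.5, MultiQC 1.7, HISAT2 2.1.0 and featureCounts 1.5.0-p3, with the genome build GRCm38. The annotation release, the feature type counted and the strand setting are not given in the sources used here. Gene symbols were found for 54723 of the 54838 identifiers, and 54809 have a position in GENCODE M21, a GRCm38 annotation from which all coordinates were taken. Of all genes counted, 31167 have 0 counts in all 6 libraries.

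The counts have a gap that limits which genes can be reported. Of 1348 protein-coding genes with no part of the gene body free of other genes on either strand, 1323 (98.1%) have 0 counts in all 6 libraries, against 19.6% of the 19568 protein-coding genes with at least 50% of the body free. The genes at 0 include abundant cardiac genes, among them Pln, Tnnc1, Actc1, Acta1, Myom1 and Cox4i1. For these genes no value is reported, and a gene whose body overlaps others in part, such as Nppa (27.2% of the body free), Myh7 (33%) or Hspa1a (25%), was counted over an unknown part of its reads. Of the 879 genes in the lists tested here, 45 are at 0 in all libraries, and 38 of these have no free part of the body. TruSeq v2 reads carry no strand, so reads of a gene and of an antisense partner cannot be told apart either.

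Total counts per library ran from 11574206 to 24138824. For single libraries, 95% Poisson intervals of the count are given, and for a count of 0 the level that 3 counts would give; both cover counting error only, since the reads carry no molecular identifiers. No pair of libraries agreed within sampling noise: chi-square per degree of freedom over genes lay between 20.4 and 69.3 for all pairs.

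The labels disagree on the genotype of 4 of the 6 libraries. The library name, which is also the column name in the table, gives one genotype, and the sample title, genotype field and mouse line give the other. Before the data were examined, the library name was chosen for the main comparison, and the genotype field for a second comparison. Below, WT and KO replicates are named by library name, with the replicate number of the title. The libraries whose genotype field says WT are WT replicate 1, KO replicate 2 and KO replicate 3, and those whose field says KO are KO replicate 1, WT replicate 2 and WT replicate 3. The library names also fall into 2 series: WT replicate 1 and KO replicate 1 have names that start with Old, and the other 4 have names that start with a number.

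Differences were tested with edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3, robust dispersion, TMM normalisation, filterByExpr), two-sided, with Benjamini-Hochberg adjustment and a threshold of adjusted p 0.05. Fold changes are given on the log2 scale as KO over WT with a standard error (SE). For edgeR the SE was derived from the test, as the absolute log2 fold change over the square root of the F statistic. CPM values are edgeR's library-size-scaled counts after TMM normalisation, and the normalisation factors lay between 0.946 and 1.028. DESeq2 1.42.0 and limma-voom (limma 3.58.1) were run as alternatives. Gene lists were fixed before the data were examined. Lists with at least 5 tested members, 41 in all, were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists. Beside these, the members past the test were counted, adjusted over all genes and adjusted over the list alone. The same fits gave every gene that is named: Prkce, the PKC family, key genes of atrial, fibrotic and coagulation biology, the 5 genes with the smallest p in each direction where fewer than 5 genes passed, genes past the threshold within 20 Mb of Prkce, and of each list the 2 to 4 members with the smallest p, named in the text only for the PKC family, the lists that camera called and lists with members past the test; genes called only in an alternative, and any other gene named outside this rule, were chosen after their values were seen.

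The alternatives covered normalisation, tool, low-count filter, a replicate block, the library series and the level of Y-linked genes as covariates, removal of genes above 1% of counts, an adjusted p threshold of 0.1, the numbered library series alone, the other label, and leaving out each library in turn. After the data were seen, 2 more were added: leaving out the 2 libraries whose Prkce level goes against their label, and keeping only genes with at least 50% of the body free. Replicate numbers are shared between the groups in the sample titles. Pairing the libraries by these numbers was planned as an alternative before the data were examined. Deviations from the group means then correlated within each pair, at 0.157, 0.162 and 0.121 across genes for the library names and at 0.269, 0.227 and 0.121 for the genotype field. By library name, each of the 6 libraries correlated best with its own number among the 3 libraries of the other group, which was not counted for the genotype field. Both libraries of replicate 1 have names that start with Old, so the size of these correlations cannot be told apart from a difference between the series. Such a difference would not by itself part replicate 2 from replicate 3, whose libraries are all in the numbered series. The labels do not say what the numbers share. Values with the block are given for Prkce, for the genes and lists by genotype field and for the list it adds by library name.

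The edgeR steps were tested on simulated data with the means and library sizes of these data. In the comparison by library name, 63% of 100 genes changed 2-fold and 91% of 100 genes changed 4-fold passed among 14427 tested genes, and 6.15% of the calls were unchanged genes. In the comparison by genotype field these values were 65%, 94% and 8.29% among 14472 tested genes. The changed genes were drawn from those above a minimum mean count. A 1.5-fold rise of 1 gene list was recovered by camera in both. Camera called 1 list in the first, the raised one, and 3 in the second, the raised one included. Each gene was simulated independently, whereas by library name the estimated correlation was 0.459 for nuclear oxidative phosphorylation and 0.832 for antigen presentation. The simulation therefore cannot show how camera at its preset correlation performs on these lists. Each simulated library also carried the change of its label, whereas the Prkce level of some libraries goes against the label in either reading. The percentages of recovered genes hold only where each library lies on the side of its label. A count of 0 genes can therefore not be read as an absence of change. Only 3 libraries per group were available, so an exact permutation test of a single value cannot give a p below 0.1, and the labels do not say more about the mice than is given here.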

Results

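The series asked how loss of PKC-epsilon, a calcium-independent serine/threonine kinase of the protein kinase C family, changes gene expression in the atria of old mice. Atrial RNA was sequenced from 6 mice, 3 labelled WT and 3 labelled KO. Total counts were 16259438, 11574206 and 24138824 in the libraries labelled WT replicate 1, 2 and 3, and 17601422, 14015308 and 20152576 in those labelled KO replicate 1, 2 and 3. Transcripts of the mitochondrial genome took 17.4% to 19.5% of the counts, and the highest gene in each library was mt-Co1, at 4.8% to 6.4%. The first principal component, with 38.4% of the variance, set the library labelled WT replicate 1 apart from the other 5.

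Prkce, the targeted gene, did not follow the labels of all libraries. The gene (ENSMUSG00000045038) lies on chromosome 17 at 86167785 to 86657919 (GRCm38), with 97.6% of its body free of other genes. Its level was 36.2 CPM (95% Poisson interval 33.4 to 39.2) in the library labelled WT replicate 1, 11.7 CPM (9.83 to 13.8) in WT replicate 2 and 30.2 CPM (28.0 to 32.5) in WT replicate 3. In the libraries labelled KO it was 9.20 CPM (7.84 to 10.7) in replicate 1, 5.15 CPM (4.02 to 6.49) in replicate 2 and 28.6 CPM (26.4 to 31.1) in replicate 3. The libraries labelled WT replicate 2 and KO replicate 3 thus went against their library names, by more than counting error. By the genotype field, the libraries at odds were KO replicate 2, whose field says WT, and WT replicate 3, whose field says KO. Prkce averaged 26.0 ± 12.8 CPM (SD, n = 3) in the libraries labelled WT and 14.3 ± 12.6 CPM in those labelled KO. In edgeR's quasi-likelihood test its log2 fold change was -0.85 (SE 0.72, adjusted p = 0.99993) by library name and -0.45 (SE 0.79, adjusted p = 0.957) by genotype field, so neither difference passed the test. With the replicate number as a block it was -1.05 (SE 0.34, adjusted p = 0.9999) by library name, lower in the library labelled KO in 3 of 3 pairs, of which the pair of replicate 3 had overlapping intervals. By genotype field the blocked value was -0.30 (SE 0.87, adjusted p = 0.955). Every direction given for KO against WT below is a direction between labels that Prkce does not bear out for 2 of 6 libraries in either reading.

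A non-coding gene close to Prkce parted the same 3 high from the same 3 low libraries; it was chosen after its values were seen. AC122818.4 (ENSMUSG00000117545, chromosome 17 at 87454969 to 87460364) starts 0.8 Mb past the end of Prkce. It had 119 counts in the library labelled WT replicate 1, 166 in WT replicate 3 and 184 in KO replicate 3, which are 7.14, 7.28 and 9.01 CPM. It had 2 counts in WT replicate 2 (0.17 CPM, 95% Poisson interval 0.0204 to 0.608). In KO replicates 1 and 2 it had 0 counts, which allow up to 0.170 and 0.218 CPM. Without the libraries labelled WT replicate 2 and KO replicate 3, a choice made from Prkce itself, 6 genes passed the test between the other 4 libraries. They were AC122818.4, Prkce (log2 fold change -2.20, SE 0.29, adjusted p = 0.0090) and, outside chromosome 17, Otud1 (-1.83, SE 0.21), Abra (-1.35, SE 0.21), Ccn5 (1.37, SE 0.21) and the processed pseudogene Gm6969 (2.04, SE 0.22). The call of Prkce in that fit is not independent evidence, since its level chose the libraries.

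**Figure D1:**
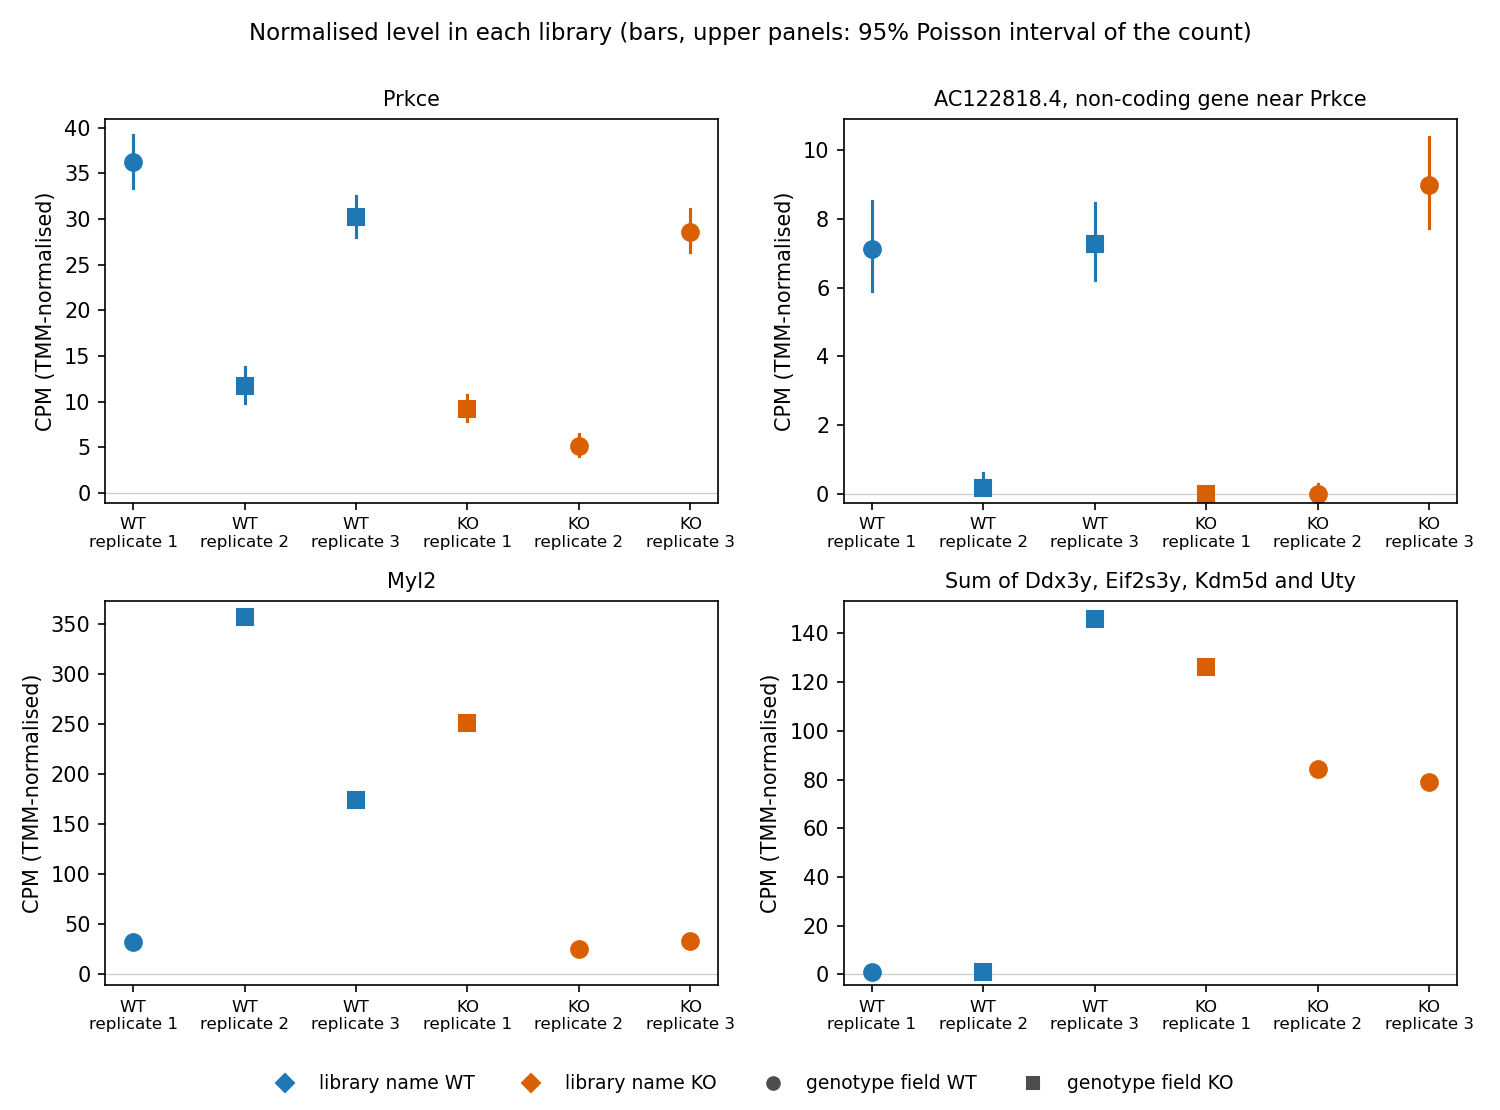
Normalised level (CPM, linear axes) of Prkce, AC122818.4, Myl2 and the sum of 4 Y-linked genes in each of the 6 libraries; colour gives the genotype in the library name, marker shape the genotype field, and bars in the upper panels 95% Poisson intervals. Prkce lies at 28.6 to 36.2 CPM in 3 libraries and at 5.15 to 11.7 CPM in the other 3, and Myl2 lies at 174 to 357 CPM in the libraries with the genotype field KO and at 25.7 to 33.4 CPM in those with the field WT.

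Genes of the Y chromosome differed between libraries of the same label. The summed level of Ddx3y, Eif2s3y, Kdm5d and Uty was 1.08 and 1.09 CPM in the libraries labelled WT replicate 1 and 2, and 146 CPM in WT replicate 3. In the libraries labelled KO it was 126, 84.1 and 78.9 CPM. By library name, the groups therefore also differed in their number of libraries with Y-linked expression, 1 of 3 against 3 of 3. By genotype field both groups held libraries of each kind. With the field WT, WT replicate 1 lacked it and KO replicates 2 and 3 had it. With the field KO, WT replicate 2 lacked it and KO replicate 1 and WT replicate 3 had it.

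The comparison by library name asked which genes change with loss of PKC-epsilon in old atria, and no gene passed the test between the libraries labelled KO and those labelled WT. The genes nearest to the threshold included Dbh, the enzyme that makes noradrenaline from dopamine, at 36.5 ± 1.5 CPM (SD, n = 3) in the libraries labelled KO and 22.5 ± 2.3 CPM in those labelled WT. Tfrc, the transferrin receptor, was at 86.5 ± 19.4 against 51.8 ± 9.9 CPM, and Rbm3, a cold-induced RNA-binding protein, at 112 ± 12 against 72.1 ± 16.2 CPM. On the other side, Dusp8, a phosphatase of MAP kinases, was at 29.0 ± 3.35 against 43.7 ± 1.4 CPM, and Hspa1a, an inducible heat shock protein with 25% of its gene body free of other genes, at 2.99 ± 0.64 against 10.6 ± 8.7 CPM, the latter resting on WT replicate 3 (20.6 CPM, against 5.22 and 5.89 CPM in WT replicates 1 and 2). Of 14708 genes tested, 0 passed in edgeR, DESeq2 or limma-voom. An unadjusted p under 0.05 was held by 219 (1.49%) in edgeR, 223 in DESeq2 and 232 in limma-voom. A uniform spread of p would give 735, but other groupings of these libraries fell on both sides of that number. Over the 10 splits of the 6 libraries into groups of 3, edgeR gave 219 to 1502 such genes, with the library name lowest. Of 111 genes tested within 20 Mb of Prkce, 0 passed in edgeR and 0 had an unadjusted p under 0.05. By genotype field 0 of the 111 passed and 3 had an unadjusted p under 0.05. Leaving out the library labelled WT replicate 1 gave 2 genes, Nfil3 and Hspb1, and leaving out WT replicate 3 gave the 4 Y-linked genes.

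The other genes among the 10 with the smallest p did not pass either. Their log2 fold changes were 1.07 (SE 0.32) for AC144797.2, 0.59 (SE 0.18) for Klhdc8a, -0.89 (SE 0.24) for Cebpb, -1.78 (SE 0.49) for Guca1b and -0.68 (SE 0.19) for Crebzf. Their adjusted p was 0.99993 in edgeR's quasi-likelihood test. All 15 genes of the PKC family were measured, 4 higher and 11 lower in the libraries labelled KO, and 0 passed, adjusted over all genes or adjusted over the list alone. Examples are Pkn2 at -0.35 (SE 0.18), Prkcb at 0.30 (SE 0.24), Prkca at -0.05 (SE 0.16) and Prkcd at 0.03 (SE 0.19).

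Among the genes of atrial stress, contraction, fibrosis and coagulation chosen beforehand, none of those described here passed. Nppa, the atrial natriuretic peptide, had 12842 ± 2860 CPM in the libraries labelled KO and 11358 ± 1233 CPM in those labelled WT, with 27.2% of its gene body free of other genes. Nppb, the B-type natriuretic peptide, had 1549 ± 691 against 1175 ± 426 CPM. The myosin heavy chain Myh6 had 9857 ± 2646 against 10617 ± 2608 CPM, and Myh7 had 149 ± 119 against 155 ± 19 CPM. The log2 fold changes of the fibrosis genes were -0.26 (SE 0.39) for Col1a1 and 0.29 (SE 0.31) for Postn. That of Thbd, the endothelial thrombin receptor, was -0.13 (SE 0.15).

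Groups of genes fixed beforehand showed small shifts that rest on single libraries and on the preset correlation of the test. Of 41 lists, camera called 9 at its preset correlation of 0.01, and 0 of the 9 held with an estimated correlation, each at adjusted p = 0.986; fry called 0. The number of members past the test, adjusted over all genes, was 0 in every list. Adjusted over the list alone it was 1 in the Schwann cell and neuronal list (Dbh) and 0 in the other 40.

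Nuclear genes of oxidative phosphorylation leaned higher in the libraries labelled KO, with 54 of 64 tested members higher and a median log2 fold change of 0.13. Examples are Uqcrh at 0.33 (SE 0.17), Ndufs4 at 0.24 (SE 0.15) and Sdhd at 0.22 (SE 0.14). The camera adjusted p was 2.7e-05 at the preset correlation and 0.986 with an estimated correlation. The library labelled WT replicate 1 alone lay low, with a list median of -0.37 on the log2 scale relative to the mean of the libraries against 0.02 to 0.12 in the other 5, and without it the adjusted p was 0.772. The 13 genes of the mitochondrial genome did not follow, with 3 higher and 10 lower, and were not called (adjusted p = 0.553).

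Genes of B and plasma cells leaned higher in the libraries labelled KO, 11 of 13, with Ighd at 0.93 (SE 0.36), Fcer2a at 0.93 (SE 0.49) and the immunoglobulin chain Ighm at 0.52 (SE 0.31). The adjusted p was 8.9e-04, and 0.986 with an estimated correlation; it was 0.0916 without the library labelled WT replicate 3 and 0.0688 without KO replicate 2. Cell cycle genes leaned the same way, 22 of 26, with Cenpe at 0.74 (SE 0.51) and Mcm6 at 0.26 (SE 0.19), while Ccnb1 was at -0.81 (SE 0.66). Their adjusted p of 0.012, and 0.986 with an estimated correlation, became 0.386, 0.224 and 0.870 without WT replicate 1, WT replicate 3 and KO replicate 2, and the last of these turned the direction. The T and NK cell list was not called (10 of 15 higher, adjusted p = 0.150).

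Stress and signalling genes leaned lower in the libraries labelled KO. Of 25 immediate early genes 22 were lower, with Klf4 at -0.42 (SE 0.14), Egr3 at -0.64 (SE 0.28) and Fosl2 at -0.52 (SE 0.25). Such genes, many of them for transcription factors, are induced within minutes of a stimulus or of tissue handling. The adjusted p of 8.9e-04 was 0.986 with an estimated correlation, 0.0725 without WT replicate 3 and 0.135 without KO replicate 2. Of 24 genes of the heat shock and unfolded protein response 19 were lower, with Hsph1 at -0.76 (SE 0.27) and Chac1, which degrades glutathione, at -0.55 (SE 0.22). Their adjusted p was 0.0030, 0.986 with an estimated correlation, 0.236 without WT replicate 3 and 0.050 without KO replicate 1; WT replicate 3 had a list median of 0.44 against -0.19 to -0.01 in the other 5 libraries. Of 17 feedback genes of ERK, JNK and NFAT signalling 16 were lower, with Gadd45g at -0.79 (SE 0.33), Spry2, an inhibitor of receptor tyrosine kinase signalling, at -0.34 (SE 0.17) and Spred2 at -0.27 (SE 0.16). Their adjusted p of 0.0084 was 0.986 with an estimated correlation, and 0.0534, 0.0502, 0.0730 and 0.364 without WT replicates 1, 2 and 3 and KO replicate 3.

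Interferon response genes leaned lower in the libraries labelled KO in 26 of 32 cases, with Irf7 at -0.49 (SE 0.20), Oasl2 at -0.44 (SE 0.19) and Ifit1 at -0.46 (SE 0.22). The adjusted p of 0.0059 was 0.986 with an estimated correlation, 0.822 without WT replicate 2 and 0.131 without KO replicate 1. Epicardial and mesothelial genes were lower in 12 of 14 cases, with the retinoic acid-producing enzyme Aldh1a2 at -0.56 (SE 0.18), the keratin Krt19 at -0.73 (SE 0.25) and Upk3b at -0.28 (SE 0.16). Their adjusted p of 0.011 was 0.986 with an estimated correlation, and 0.118, 0.233 and 0.555 without WT replicate 2, WT replicate 3 and KO replicate 1. Megakaryocyte and platelet genes were lower in 8 of 9 cases, with Gp9 at -1.32 (SE 0.62), Ppbp at -0.98 (SE 0.45) and Tubb1 at -1.19 (SE 0.71), all at low levels of 0.145 to 11.9 CPM. Their adjusted p of 0.0057 was 0.986 with an estimated correlation, 0.0738 without WT replicate 2 and 0.339 without KO replicate 2.

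The remaining 32 lists were not called; for those named here the members higher in the libraries labelled KO are given with camera's adjusted p. For glycolysis and NRF2 targets the mean log2 fold change was below 0 while the median was above it, and for mitophagy, macrophage and antigen presentation genes camera's direction was up with a median below 0. Among the cardiomyocyte lists, the atrial list had 10 of 18 members higher (adjusted p = 0.937), the ventricular list 4 of 14 (0.587), the sinoatrial node list 3 of 12 (0.847), the sarcomere list 6 of 21 (0.914), the hypertrophy list 8 of 17 (0.914) and the calcium handling and ion channel list 20 of 43 (0.937). Collagen and fibrosis genes had 14 of 37 higher (0.959), fibroblast genes 3 of 12 (0.438), and genes of coagulation and the anticoagulant endothelium 11 of 29 (0.318). Fatty acid oxidation had 14 of 37 higher (0.847), glycolysis 15 of 27 (0.847), the TCA cycle 17 of 25 (0.349), NRF2 targets 16 of 27 (0.806) and mitophagy 9 of 24 (0.957). Inflammatory cytokines and chemokines had 10 of 24 higher (0.912), macrophage genes 9 of 20 (0.851) and senescence genes 7 of 20 (0.806). Neutrophil and mast cell genes had 5 of 9 higher (0.959), antigen presentation 6 of 12 (0.912), erythroid genes 1 of 6 (0.742), circadian clock genes 5 of 16 (0.814) and lipid synthesis and insulin signalling genes 11 of 24 (0.912). Endothelial genes had 7 of 17 higher (0.806), smooth muscle and pericyte genes 7 of 13 (0.937), white adipocyte genes 9 of 14 (0.893), brown adipocyte genes 6 of 7 (0.391), skeletal muscle genes 4 of 8 (0.912) and chondrocyte and valve genes 1 of 7 (0.318).

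Schwann cell and neuronal genes were higher in the libraries labelled KO in 10 of 14 cases, and whether they were called depended on the replicate block and on single libraries. Their adjusted p in camera was 0.244 without the block and 0.0072 with it, which took the number of called lists from 9 to 10; the latter was 0.874 with an estimated correlation. Without the block it was 0.0044 without WT replicate 2 and 0.0014 without KO replicate 1, and the direction turned without KO replicate 2 (adjusted p = 0.367). The list median was 0.98 in KO replicate 2 and 0.54 in WT replicate 2, against -0.41 to -0.06 in the other 4 libraries. White adipocyte genes were also highest in these 2 libraries, with medians of 0.892 and 0.492, against -0.851 to 0.414 in the other 4.

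**Figure D2:**
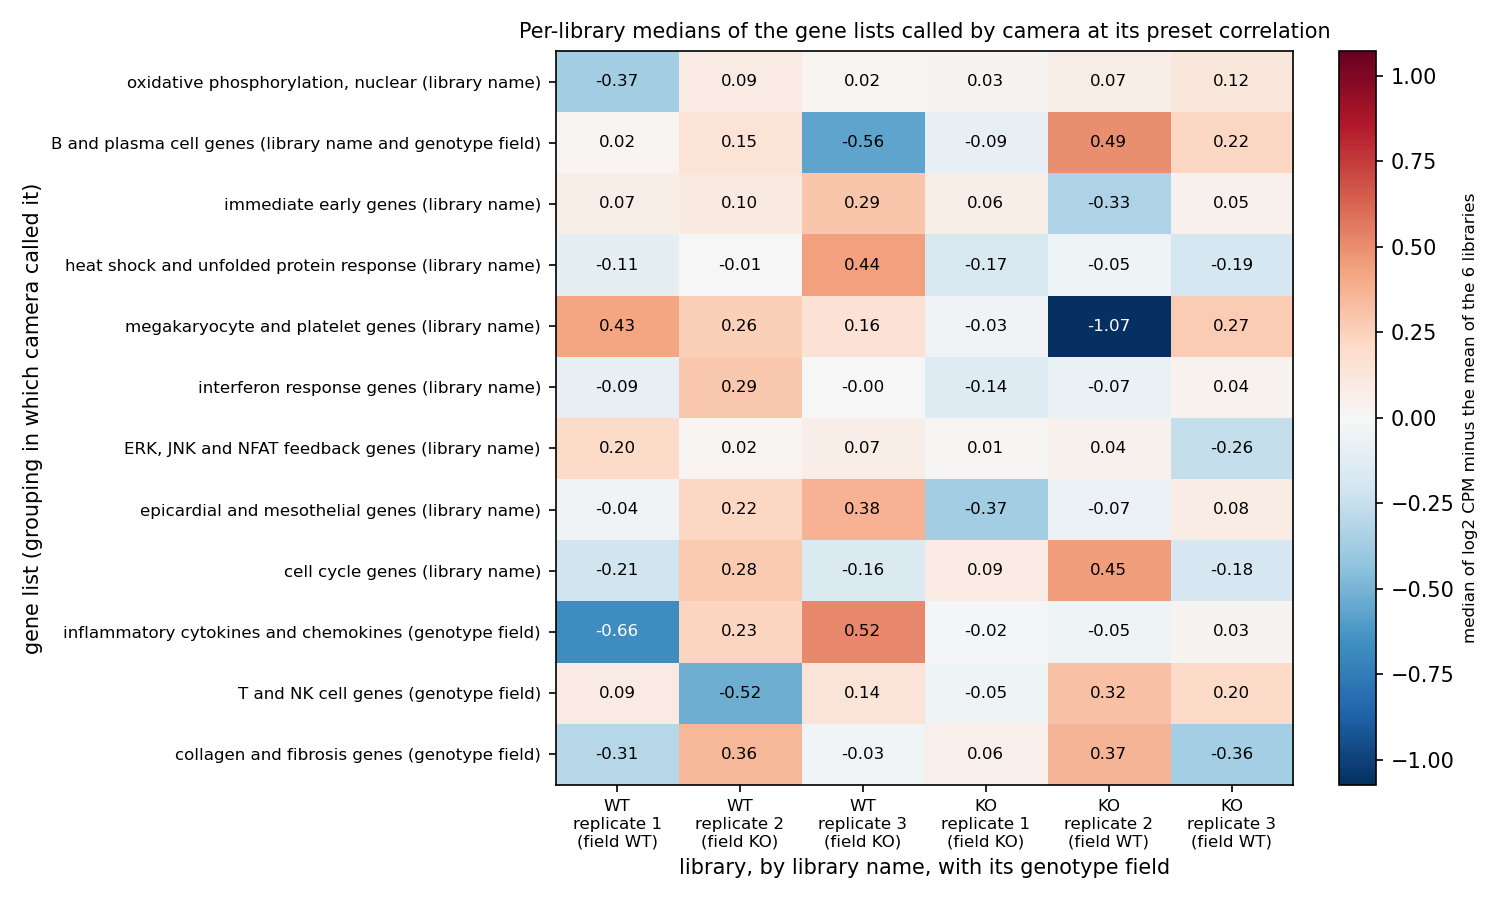
Median over the tested members of each gene list called by camera at its preset correlation (y axis, with the grouping that called it) in each library (x axis), as log2 CPM minus the mean of the 6 libraries. In several lists single libraries stand out, such as WT replicate 1 at -0.37 for oxidative phosphorylation and KO replicate 2 at -1.07 for megakaryocyte and platelet genes.

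By the genotype field, the clearest difference was in a myosin light chain of ventricular muscle. Myl2, the regulatory light chain of ventricular muscle, was at 261 ± 92 CPM (SD, n = 3) in the libraries with the field KO and 30.6 ± 4.2 CPM in those with the field WT, a log2 fold change of 3.09 (SE 0.25, adjusted p = 0.0039 in edgeR's quasi-likelihood test), higher in 3 of 3 libraries. The lincRNA Gm26917 (chromosome 17 at 39843013 to 39846341) was at 26.0 ± 6.4 against 6.61 ± 0.72 CPM, a log2 fold change of 1.97 (SE 0.22, adjusted p = 0.015). These 2 genes passed, both higher, of 14708 tested; Apba3 (1.11, SE 0.15) passed only at an adjusted p under 0.1, and 837 genes had an unadjusted p under 0.05. DESeq2 called 27 genes and limma-voom 1, Myl2. The count was 0 without the library labelled WT replicate 1 or KO replicate 3, where Myl2 stood at adjusted p = 0.146 and 0.0707, and it was 1, Myl2, without WT replicate 2, WT replicate 3 or KO replicate 2. The adjusted p of Gm26917 was 0.0736, 0.102, 0.165, 0.1098 and 0.267 without WT replicates 1, 2 and 3 and KO replicates 2 and 3, and that of Myl2 was 0.344 in the numbered library series alone. The log2 fold changes moved little in these fits: Myl2 was at 3.13 without WT replicate 1, 3.16 without KO replicate 3 and 3.16 in the numbered series, and Gm26917 ran from 1.81 to 2.15 leaving out 1 library. Without the 2 libraries whose Prkce level goes against their field, KO replicate 2 and WT replicate 3, 3 genes passed, Myl2 higher and Otud1 and AC122818.4 lower.

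The other genes nearest to the threshold did not pass in this fit. Myl3, the essential light chain of ventricular and slow muscle, was at 1.20 (SE 0.19) and the neutrophil-attracting chemokine Cxcl1 at 1.01 (SE 0.18). Lower in the libraries with the field KO were the immunoglobulin joining chain Jchain at -1.32 (SE 0.25), the integrin Itgax at -1.13 (SE 0.26), the adipocyte hormone Lep at -2.48 (SE 0.59), Ighm at -0.83 (SE 0.21) and Zfp715 at -0.60 (SE 0.16). In the ventricular list 2 of 14 members, Myl2 and Myl3, passed when adjusted over the list alone and 1 over all genes, while 8 were higher and 6 lower. With the replicate number as a block, 51 genes passed, 48 higher and 3 lower in the libraries with the field KO. The smallest p were those of Gm24187 (2.57, SE 0.21), D130009I18Rik (2.05, SE 0.16) and Rpl36 (1.44). Of the 48, 31 were lowest in the library labelled WT replicate 1, 11 in KO replicate 2 and 6 in KO replicate 3, the 3 libraries with the field WT. The higher ones included Myl2 (3.03, SE 0.26), Myl3 (1.20, SE 0.13), Cxcl1 (1.03, SE 0.15), Cxcl2 (2.05, SE 0.32) and Col1a1 (0.76, SE 0.14), and the lower ones Jchain (-1.29, SE 0.23) and Ighm (-0.78, SE 0.15). Of the lists fixed beforehand, the inflammatory list and the immediate early list each had 3 members among the 51, and the ventricular list and the B and plasma cell list 2 each. The PKC family had 7 of 15 members higher by the genotype field (camera adjusted p = 0.968), and 0 passed. Of the genes chosen beforehand, Nppa was at 0.08 (SE 0.19), Nppb at -0.18 (SE 0.40), Myh6 at 0.16 (SE 0.23), Myh7 at -0.30 (SE 0.59), Postn at -0.24 (SE 0.32) and Thbd at 0.01 (SE 0.15) by genotype field, and none of these passed.

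Of the 41 lists, camera called 4 by the genotype field, and none held with an estimated correlation, each at adjusted p = 0.984; fry called 0. Inflammatory cytokines and chemokines were higher in 18 of 24 cases in the libraries with the field KO (adjusted p = 0.0016, and 0.984 with an estimated correlation), with Cxcl1 as the 1 member past the test adjusted over the list alone and Cxcl2, a neutrophil-attracting chemokine, at 1.91 (SE 0.60). With the replicate block this list had an adjusted p of 3.3e-05, and 0.652 with an estimated correlation, with 9 of 24 members past the test adjusted over the list alone and 3 over all genes. The call was lost without WT replicate 1 (adjusted p = 0.0850) or WT replicate 3 (0.0591), and the list median was -0.66 in WT replicate 1 and 0.52 in WT replicate 3. Collagen and fibrosis genes were higher in 27 of 37 cases, with Col16a1 at 0.61 (SE 0.24), Col5a1 at 0.50 (SE 0.19) and Col1a1 at 0.72 (SE 0.29). Their adjusted p of 0.039 was 0.984 with an estimated correlation, and 0.368, 0.312, 0.0591 and 0.761 without WT replicates 1, 2 and 3 and KO replicate 3, while without KO replicate 2 it was 6.8e-09. The list median was highest in KO replicate 2 (0.368), whose field says WT, against the direction of the list, and lowest in WT replicate 1 (-0.307) and KO replicate 3 (-0.361).

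Lymphocyte genes leaned lower in the libraries with the field KO, and adipocyte and neuronal genes, which were not called, lay lower as well. T and NK cell genes were lower in 10 of 15 cases, with Cd28, a co-stimulatory receptor, at -0.92 (SE 0.42) and Nkg7 at -0.87 (SE 0.43); the adjusted p of 0.021 was 0.984 with an estimated correlation, and 0.0583, 0.0514 and 0.0643 without WT replicate 2, KO replicate 2 and KO replicate 3. B and plasma cell genes were lower in 9 of 13 cases, with 2 members past the test adjusted over the list alone and Iglc2 at -1.03 (SE 0.40). Their adjusted p of 0.038 was 0.984 with an estimated correlation, and 0.286, 0.290 and 0.0643 without WT replicate 3, KO replicate 2 and KO replicate 3. With the block, camera called 6 lists by the genotype field, among them antigen presentation (adjusted p = 0.025, and 0.866 with an estimated correlation) and macrophage and monocyte genes (0.046, and 0.992 with an estimated correlation).

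The other 37 lists were not called by the genotype field, with adjusted p from 0.0641 to 0.968. Nearest to the threshold were antigen presentation, with 11 of 12 members higher in the libraries with the field KO (0.0641), sarcomere genes with 16 of 21 (0.0641), skeletal muscle genes with 7 of 8 (0.0663), nuclear genes of oxidative phosphorylation with 39 of 64 (0.0681) and immediate early genes with 18 of 25 (0.0884). White adipocyte genes and Schwann cell and neuronal genes were each lower in 10 of 14 cases (0.258 each). The library labelled KO replicate 2, whose field says WT, had the highest list median of the 6 libraries for B and plasma cell genes (0.495), white adipocyte genes (0.892) and Schwann cell and neuronal genes (0.98). Adjusted over the list alone, 1 member passed in each of 4 lists that camera did not call: Mt1 among NRF2 targets, Junb among immediate early genes, Gadd45b among ERK, JNK and NFAT feedback genes and Lep among white adipocyte genes.

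With the 2 series of library names as a covariate, 0 genes passed in edgeR between the libraries labelled KO and those labelled WT, with 308 at an unadjusted p under 0.05. With this covariate 17 genes passed with no low-count filter, and 7 passed by the genotype field. The series themselves were not compared. In the numbered series alone, 2 libraries against 2, 3 genes passed, Gm24187, Gm26917 and D130009I18Rik, each lower in the libraries labelled KO and, since the genotype field reverses all 4 of these libraries, higher in those with the field KO. The series whose names start with Old holds 1 library per genotype, so it gives no test of its own.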

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

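The alternatives that leave out the 2 libraries at odds with Prkce, or keep genes with at least 50% of the body free, were chosen after seeing the data. The count of genes by library name was 0 with either normalisation, DESeq2, limma-voom, the stricter filter, the replicate block and the covariates. It was 1 with no low-count filter (Igkv8-24), 2 under the other label, 3 in the numbered library series alone, 6 without the 2 libraries at odds with Prkce, and 0 to 4 leaving out 1 library. The log2 fold change of Prkce stayed below 0 by library name, from -2.201 to -0.301, and passed the test only without the 2 libraries at odds with it, at -2.201; by genotype field it ran from -1.647 to 0.301, the last in the numbered series alone. The count of called lists by library name was 0 with an estimated correlation or fry, 4 under the other label and 3 to 10 leaving out 1 library.

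By genotype field the gene count was 27 with DESeq2, which gave no adjusted p for 5704 genes, 1 with limma-voom, 25 with no low-count filter, 51 with the replicate block, 7 with the library series as covariate, 0 under the other label and 0 to 2 leaving out 1 library. The list count was 0 with an estimated correlation or fry, 9 at an adjusted p under 0.1, 10 with limma-voom, 1 with the series covariate, 9 under the other label, 9 in the numbered series alone, 9 without the 2 libraries at odds with Prkce and 1 to 11 leaving out 1 library. With the series as covariate the count by library name, 0, was 17 with no low-count filter and 7 under the other label. Under the other label Myl2 (-0.859) and Gm26917 (-1.07) reversed. For all of these the cause was not tested. Across the named genes other than Prkce and the alternatives, 1769 values kept their direction and their side of the threshold, which for most means not passing. Another 135 changed direction without passing in either fit, however small the change. A further 10 lost their call, 18 gained one, and 2 changed direction with a call in at least 1 of the fits. Depth, 11574206 to 24138824 counts, limits genes near 0 such as Gp9 and AC122818.4.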

Other observations

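All tests in this part were chosen only after the results were seen.

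Prkce went against the library names of WT replicate 2 and KO replicate 3. Counting error at Prkce was argued against by the ratio of WT replicate 2 to WT replicates 1 and 3, 0.3573 (95% interval 0.2977 to 0.4258). RNA of the targeted allele counted over the gene body stays open: Prkce in KO replicate 3 was 3.8587 times that in KO replicates 1 and 2 (3.3096 to 4.511), but these 2 mice already differed from each other beyond counting error. A candidate explanation is a swap of WT replicate 2 and KO replicate 3: of 5 genes other than Prkce called between the other 4 libraries, all 10 of 10 values in the 2 left-out libraries lay past the midpoint on the side of the other genotype. These values come from 2 mice and are not independent. Some lay near the midpoint, such as Abra at 0.6 in WT replicate 2 and Ccn5 at 0.33 in KO replicate 3, where 0 is the WT and 1 the KO mean. By the genotype field, a swap of KO replicate 2 and WT replicate 3 would part the libraries in the same way, so the 10 values cannot tell the 2 swaps apart. Of 3 genes called without KO replicate 2 and WT replicate 3, 4 of 6 values lay past the midpoint, those of Otud1 and AC122818.4. Myl2 stayed with the field in both, so this test left the swap by genotype field open. AC122818.4 lies near Prkce, so it may carry the strain around the targeted gene, which was not tested directly. Counts of nearby genes did not decide it. Grouped as Prkce parts the libraries, 10 of 111 genes within 20 Mb had an unadjusted p under 0.05 in edgeR, and 1, AC122818.4, passed. WT replicates 1 and 3 and KO replicate 1 against the rest gave 12. WT replicate 1 and KO replicates 1 and 2 against the rest gave 13, with 0 passing in both splits. Another structure shared by the same libraries stays open, as does where a swap would have arisen. The libraries were not regrouped.

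Abundant cardiac genes, such as Pln, Tnnc1 and Actc1, had 0 counts in every library. Reads dropped only where exons overlap were argued against, since 98.688% of nested genes with all exon bases free were at 0. Competition by genes on the same strand alone was argued against, since 99.069% of genes nested only in genes of the other strand were at 0. Reads counted over whole gene bodies without strand and dropped where genes overlap may explain the pattern: 98.145% of nested protein-coding genes were at 0. No biological explanation was tested.

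Myl2 and Myl3 were higher in the libraries with the genotype field KO. More ventricular tissue in those libraries could raise both, but the other 12 tested ventricular genes had a median log2 fold change of -0.0093 (range -0.304 to 0.4387). This cannot be told apart from a change in these genes, because 9 of the 12 exceed 30 CPM in the libraries with the field WT (median 159 CPM), and such a baseline would hide a small share. Myl2 did not follow Prkce: it was at 174 CPM in WT replicate 3, with Prkce at 30.2 CPM, and at 25.7 CPM in KO replicate 2, with Prkce at 5.15 CPM. An effect of the genotype stays open, given the conflict of the labels.

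The 6 libraries make 10 splits into groups of 3, too few for a share under 0.05. As many genes as by library name (0) came from 10 of 10 splits, which a count of 0 gives whatever the data. As many as by genotype field (2) came from 3 of 10, with 6 as the highest other count. That split, WT replicates 1 and 3 and KO replicate 3 against the rest, parts the libraries as Prkce does, and its 6 genes include Prkce and AC122818.4. At an unadjusted p under 0.05 it had 965 genes, and 3 other splits had more (1502, 1134 and 1074). As many lists as by library name (9) came from 7 of 10 splits and as many as by genotype field (4) from 10 of 10, with 19 as the highest other. With the replicate block 4 splits part all pairs, again too few. The genotype field gave 51 genes, as many in 1 of 4, with 1 as the highest other. The library name gave 0, as many in 4 of 4, which again holds for 0 whatever the data, with 51 as the highest other.

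Some values belong in no comparison and were chosen after they were seen. Ucp1, the uncoupling protein of brown fat, was at 57.4 CPM in the library labelled KO replicate 2 and at 0 to 3.54 CPM in the other 5.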
